A study of Macaca fascicularis with 12 samples.

How the data were processed

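Gene expression was measured in iliac artery tissue of 12 female cynomolgus monkeys (Macaca fascicularis), 1 artery and 1 array per animal, so that replicates were separate animals. Per the labels, the ovaries had been removed 4 years and a high fat diet begun 8 years before sampling. The submitters measured plaque area in each artery and sorted the animals into small (n = 4), medium (n = 5) and large (n = 3) plaque. The labels call each sample an iliac artery biopsy. Below, medium or large plaques is short for the arteries of that group and does not mean plaque tissue alone. Of the small group, 2 animals had no plaque and were given an area of 0. Small replicate 4 and medium replicate 5 have identity numbers in the labels that lie far from those of the other 10 animals. The labels give no batch or cohort, so whether these 2 came from another one is not known here. Counts of called probes and of called lists were also computed without them, but not the calls shared by the comparisons against small.

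Per the labels' protocols, total RNA was amplified to biotinylated cRNA, hybridized to CodeLink arrays of human probes, stained with a single dye and scanned. The deposited values are linear probe intensities that the authors had scaled so that the median of each array lay close to 1, as the values themselves show. Some values lie below 0, so background had been subtracted at some step. The image software, the background method and the scaling formula are not given in the sources used here. The probes were designed for human transcripts, so a mismatch to the monkey sequence can lower a probe's signal. Differences were therefore taken between animals for the same probe. Levels of probes were set against each other only to choose the probe of a gene and to tell bright from dim probes. The number of arrays limits the precision.

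The table held 54359 probes, of which 479 were empty on every array. Probes with values in at least 2 animals of each group were kept, which left 53877, and 293 of these lacked a value on at least 1 array. Intensities below the 5th percentile of the positive values, 0.111, were set to it before taking log2, which affected 5.45% of the values. A difference from a group at this floor is understated. The array medians lay together on the log2 scale, so no further normalization was applied. Gene names came from the platform's annotation, which can be old. Among the tested probes 23267 had 1 gene symbol, 900 had several and 29710 were unnamed here. No gene was named from a probe with several symbols. Of the 18160 distinct symbols, 14595 also appear in the annotation of the macaque assembly T2T-MFA8v1.1, which was used for names only.

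Each probe was tested with limma version 3.58.1 in R version 4.3.3, by lmFit with 3 group means over all 12 arrays and eBayes. P-values are two-sided and were adjusted by Benjamini-Hochberg over all tested probes, with a threshold of 0.05. A moderated F test covered any difference among the groups, and a second fit gave the slope of log2 intensity per mm2 of plaque area. Differences are given with the standard error (SE) of the fit. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, 1 probe per gene, namely the brightest probe with values on every array. The 31 lists comprised 13 sets of cell type markers and 18 other gene groups, and no gene was in more than 1 list. Adjustment was over the 30 lists with at least 5 measured members; of the red blood cell list 4 members were measured. Camera was repeated with the correlation estimated from the data, and fry was run beside it. List scores, the mean of the members centred on their own means, were set against plaque area with permutation tests of 100000 resamples.

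The design, the lists and the rule for named genes were fixed before the data were examined. Named were the 8 single-symbol genes with the largest rise and the 8 with the largest fall among the called ones, with 4 each way in large against medium, filled by smallest p where none passed. Up to 4 members per list with a p under 0.05 adjusted over the list alone were added, or the 2 of smallest p, and ACTA2, MYH11, CD68, CD163, SPP1, VCAM1, CCL2, ESR1, MMP9, COL1A1 and PECAM1 could be named in any comparison. A gene among the largest changes was represented by its probe of smallest p, other genes by the brightest probe, and the text names only part of the genes this rule allows. The alternatives covered the normalization, the floor, dim and incomplete probes, the probe per gene, the variance model, array weights, thresholds, the samples in the fit, the scale of plaque area, the replicate number as a block, and each animal left out in turn. The 3 comparisons of groups and the slope were tested on simulated data for the 53877 probes, drawn independently, with 200 changed per run. The F test and the scores were not tested this way. False calls made up 5.57% of calls for large against small, 3.06% for medium against small, and 4.41% for large against medium and for the slope. For large against small, 15.4% of changes of 1 log2 unit, 75.2% of changes of 2 and 94.9% of changes of 3 were called. For medium against small the shares were 25.4%, 85.8% and 97.8%, for large against medium 17.1%, 80.6% and 94.9%, and for slopes of those sizes per mm2 6.01%, 62.5% and 89.5%. Figures were drawn with matplotlib version 3.10.9.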

Results

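The series recorded transcript levels in the iliac artery of 12 monkeys on a long high fat diet, with the size of atherosclerotic plaque as the experimental factor. Plaque area ran from 0 to 0.113 mm2 in the small group, from 0.30 to 0.542 mm2 in the medium group and from 0.61 to 1.003 mm2 in the large group. Between 53832 and 53867 probes had a value on each array. Arrays of the same group correlated with a median r across probes of 0.947 in small, 0.967 in medium and 0.967 in large, against 0.939 between large and small. These correlations are across probes, which are not independent replicates. The first principal component held 25.1% of the variance and placed all 4 small arrays between -90.9 and -55.2 and the other 8 between 13.5 and 84.6. No 2 arrays were duplicates. Small replicate 1 had the highest 99th percentile of intensity, 195.8, against 114.2 to 147.6 on the others.

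Arteries with large plaques were compared with those with small plaques first, the extremes of the design. The 8 largest rises in large plaques included genes of the macrophage list, LAPTM5 and LYZ. LAPTM5, a lysosomal membrane protein of blood cells, rose by 4.95 ± 0.61 log2 units (SE, n = 3 and 4) with 1 small array at the floor, and LYZ, the secreted lysozyme of phagocytes, by 4.71 ± 0.60. CTSS, the lysosomal protease cathepsin S, rose by 4.69 ± 0.55. GDF15, a stress-induced cytokine, rose by 5.46 ± 0.48, and MATK, a tyrosine kinase of blood cells, by 5.91 ± 0.54 from a small group with 2 of its 4 arrays at the floor. Outside the 8 largest, the fatty acid carrier FABP5 rose by 3.94 ± 0.39 and the chemokine CXCL8, interleukin 8, by 3.83 ± 0.45.

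Among the other largest rises were MLPH, an adaptor of organelle transport, at 4.99 ± 0.43 on 1 of its 2 probes, ADAMDEC1 at 4.88 ± 0.77 and CRABP2, a retinoic acid carrier, at 4.80 ± 0.71. The falls were smaller. IGSF21 fell by 3.22 ± 0.68, followed by IGSF10 at -3.21 ± 0.42, EDN3, which encodes endothelin 3, at -2.55 ± 0.45 on the brighter of its 2 probes, and the collagen gene COL27A1 at -2.46 ± 0.35 on 1 of its 3 probes. ECRG4 at -2.38, CHODL at -2.23, BMP5 at -1.92 with 2 large arrays at the floor, and COL13A1 at -1.83 also fell. The calls of IGSF21, ECRG4 and CHODL were lost under 13, 13 and 12 of 23 alternatives, whereas those of LAPTM5, LYZ, CTSS, GDF15, MATK and IGSF10 held under all 23.

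Of 18 measured macrophage markers 10 rose over all probes tested, and 13 rose and 1 fell adjusted over the list alone, MARCO, named after its values were seen. TYROBP rose by 3.07, CD86 by 3.18, ITGAX by 2.80 and the haemoglobin scavenger receptor CD163 by 2.37 log2 units. CD68, a lysosomal glycoprotein used to stain macrophages, did not follow, with -0.66 ± 0.51 and an adjusted p of 0.565 on its only probe. The list was called by camera, with an adjusted p of 1.23e-10, but its adjusted p was 0.0774 with an estimated correlation.

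Foam cell and lipid handling genes rose in 12 of 22 cases, and in 17 adjusted over the list alone, among them FABP5, APOC1 at 3.56, LGALS3 at 3.04 and, on the brighter of its 2 probes, the lysosomal protease CTSB at 4.68. Camera called the list, with an adjusted p of 0.0774 once the correlation was estimated. In MHC class II presentation 5 of 10 rose, and 6 adjusted over the list alone, with HLA-DPB1 at 3.52, HLA-DMA at 1.79, HLA-DMB at 1.46 and HLA-DQB1 at 2.48. HLA-DRA, at 1.53 on the brighter of its 2 probes, was named after its values were seen, and its call was lost under 10 of 23 alternatives. That list was called, with an adjusted p of 0.0774 with an estimated correlation. HLA genes of 1 family resemble each other, so a probe for one may bind transcripts of another.

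Matrix proteases and inhibitors rose in 7 of 20, and 9 rose and 3 fell adjusted over the list alone, the last being ADAMTS1, ADAMTS4 and CST3, named after their values were seen. CTSL rose by 1.93, the urokinase gene PLAU by 1.94 and MMP19 by 2.21, while MMP9 differed by 0.41 ± 0.22 (adjusted p 0.4). The list was called, with an adjusted p of 0.09 with an estimated correlation. Of the oxidative stress genes 5 of 16 rose, and 9 adjusted over the list alone, including GPX1 by 2.39, GPX3 by 1.95, HMOX1, haem oxygenase 1, by 1.97, NCF4, a subunit of the phagocyte oxidase, by 2.76 and CYBA, another subunit named here after its values were seen, by 3.22. Its adjusted p was 0.115 with an estimated correlation. Among adhesion molecules and chemokines 2 of 20 rose, CXCL8 and CCL2, the latter by 1.51, and 5 adjusted over the list alone, while VCAM1 differed by 0.04 ± 0.23. Its adjusted p was 0.09 with an estimated correlation.

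None of 13 T cell markers rose over all probes tested and 4 did adjusted over the list alone, of which GZMA differed by 2.28 and CD27 by 1.83. The list was called, with an adjusted p of 0.306 with an estimated correlation. Contractile smooth muscle was the list called as lower, but its adjusted p was 0.384 with an estimated correlation, and fry did not call it. MYLK, myosin light chain kinase, fell by 1.48 ± 0.31 on the brighter of its 2 probes, the only 1 of 16 measured members to do so, over all probes and adjusted over the list alone, and its call was lost under 11 of 23 alternatives. ACTA2 at -0.59 ± 0.42 and MYH11 at -0.37 ± 0.20 did not pass.

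In all, 617 of 53877 probes were called, 511 higher and 106 lower, and 8 of 30 lists, 7 higher and 1 lower. None of the 8 was called with an estimated correlation. The probe count was 112 without large replicate 3, 132 without large replicate 1, 261 without small replicate 2, 1216 without small replicate 1 and 316 without both small replicate 4 and medium replicate 5, the 2 animals whose identity numbers lie apart from those of the other 10. The other 22 lists had adjusted p-values from 0.0647 to 0.989, and among their members PECAM1 of endothelium at -0.06 and COL1A1 of the collagens at 0.11 differed little on the probes used. A dim probe of PECAM1 rose by 1.25 (limma adjusted p 0.0486), and a brighter probe of COL1A1 differed by 0.40 (limma adjusted p 0.67).

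Arteries with medium plaques were compared with those with small plaques next. CYP27A1, a mitochondrial sterol hydroxylase, rose by 4.33 ± 0.28 (SE, n = 5 and 4), LY86, a partner of a toll-like receptor relative, by 4.43 ± 0.37 and GDF15 by 5.47 ± 0.42. FABP5 rose by 4.33 ± 0.34, SOD2, the mitochondrial superoxide dismutase, by 4.00 ± 0.39 and CXCL8 by 3.81 ± 0.39. IGSF10 fell by 3.86 ± 0.37 and SMTN, which encodes the smooth muscle protein smoothelin, by 2.39 ± 0.47.

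MLPH rose by 4.94, MATK by 4.91, ADAMDEC1 by 4.85, LAPTM5 by 4.83 and CRABP2 by 4.57. Other large falls were IGSF21 at -3.16, COPG2IT1 at -3.07, ADAM33 at -2.86, EDN3 at -2.81, KCNB2 at -2.62 and ITM2A at -2.39. Of 18 macrophage markers 11 rose, and 13 rose and 1 fell adjusted over the list alone, with CD86 at 3.22, TYROBP at 3.11, ITGAX at 2.71 and CD163 at 2.68, while CD68 differed by -0.44 ± 0.45. The list's adjusted p was 0.0556 with an estimated correlation.

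Of 22 foam cell and lipid handling genes 15 rose, and 18 adjusted over the list alone, with APOC1 at 4.06, LGALS3 at 2.66 and NPC2 at 1.90. SPP1, osteopontin, rose by 3.27 ± 0.65 from a small group with 1 array at the floor. MHC class II genes rose in 5 of 10, and in 8 adjusted over the list alone, with HLA-DRA at 2.05 on the brighter of its 2 probes, HLA-DPB1 at 2.79, HLA-DMA at 2.04 and HLA-DMB. The other, HLA-DQB1 at 1.66, was named after its values were seen, and its call was lost under 12 of 23 alternatives. Adhesion molecules and chemokines rose in 4 of 20, and in 9 adjusted over the list alone, namely over all probes CCL2 by 2.27, CCL8 by 2.85, CCL18 by 1.54 and CXCL8. The call of CCL18 was lost under 13 of 23 alternatives. Each of these lists was also called with an estimated correlation, at an adjusted p of 0.0443.

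Of the proliferation genes 6 of 18 rose, and 7 adjusted over the list alone, with UBE2C, a mitotic ubiquitin carrier, at 2.33, BIRC5, survivin, at 1.48, TYMS at 1.48 and CCNA2 at 1.06. The adjusted p was 0.117 with an estimated correlation. T cell markers rose in 2 of 13, GZMA at 2.53 and CD27 at 1.66, the latter call lost under 10 of 22 alternatives, and in 7 adjusted over the list alone (adjusted p 0.117 with an estimated correlation). Oxidative stress genes rose in 4 of 16, HMOX1, GPX1, GPX3 and NCF4, and 10 rose and 1 fell, SOD1, adjusted over the list alone (adjusted p 0.117 with an estimated correlation). In matrix proteases and inhibitors 6 of 20 rose and 2 fell, and 13 rose and 3 fell adjusted over the list alone, with PLAU at 2.43, CTSS at 3.96 and CTSL at 2.21. Those that fell were the inhibitors TIMP3 at -0.70, a call lost under 14 of 23 alternatives, and CST3 at -1.58, and over the list alone ADAMTS1, named like SOD1 after their values were seen (adjusted p 0.0888 with an estimated correlation).

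The contractile smooth muscle list was called as lower, but its adjusted p was 0.181 with an estimated correlation. Of its 16 measured members 2 fell over all probes, SMTN and MYLK, the latter by 1.61 ± 0.27, and 11 adjusted over the list alone. For both genes the dimmer of 2 probes did not pass. MYH11 at -0.67 and ACTA2 at -0.61 did not pass over all probes.

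PGR, the progesterone receptor, fell in arteries with medium plaque by 1.76 ± 0.32 and ESR1, oestrogen receptor alpha, by 1.30 ± 0.28. NRIP1, a corepressor of nuclear receptors, rose by 1.17 ± 0.26 on the brighter of its 2 probes. These were the 3 called of 15 measured in that list, with 1 risen and 3 fallen adjusted over the list alone, HSD17B2 being the third. Camera did not call the list (adjusted p 0.35), whereas fry, which does not compare a list with other genes, called it as lower (adjusted p 0.0294). The calls of ESR1 and NRIP1 were lost under 7 and 9 of 23 alternatives. In large plaques ESR1 at -1.02 and PGR at -1.22 did not pass over all probes. Vasoactive genes AGTR1, the angiotensin receptor, TBXA2R and KCNMA1 stood at -1.70, -1.46 and -1.14, each past the threshold, in a list that camera did not call (adjusted p 0.0502) and fry called as lower (adjusted p 0.018), and the call of TBXA2R was lost under 11 of 23 alternatives.

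In medium against small 1693 probes were called, 1062 higher and 631 lower, and 9 lists, 8 higher and 1 lower, of which 3 held with an estimated correlation. The probe count was 847 without small replicate 2, 958 without medium replicate 1, 972 without medium replicate 4, 1011 without medium replicate 5 and 773 without both animals whose identity numbers lie apart. The other 21 lists had adjusted p-values from 0.0502 to 0.911. Among them were markers of endothelium (median -0.15), adventitial fibroblast (-0.287), adipocyte (-0.121), mast cell (-0.201) and skeletal muscle (-0.192), and collagens and plaque matrix (-0.191).

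Several probes were present for 29 of the 119 genes examined, and in medium against small the probes had opposite signs for 12 of them and differed in call for 20. For MYLK, SMTN, SOD2, TLR4, NRIP1, SMAD4, NR4A1, MMP19, COL27A1 and KCNMA1 a probe of opposite sign did not pass, and PECAM1 rose by 1.21 on a dim probe only. A probe of the same sign did not pass for MLPH, CTSS, GPNMB, HLA-DMA, HLA-DRA, ID1, LDHA, PGR and TIMP3. In large against small the other probe of CTSB differed by 1.05 (adjusted p 0.134) and that of EDN3 by -1.47 (adjusted p 0.087), while both probes of each were called in medium against small.

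**Figure D1:**
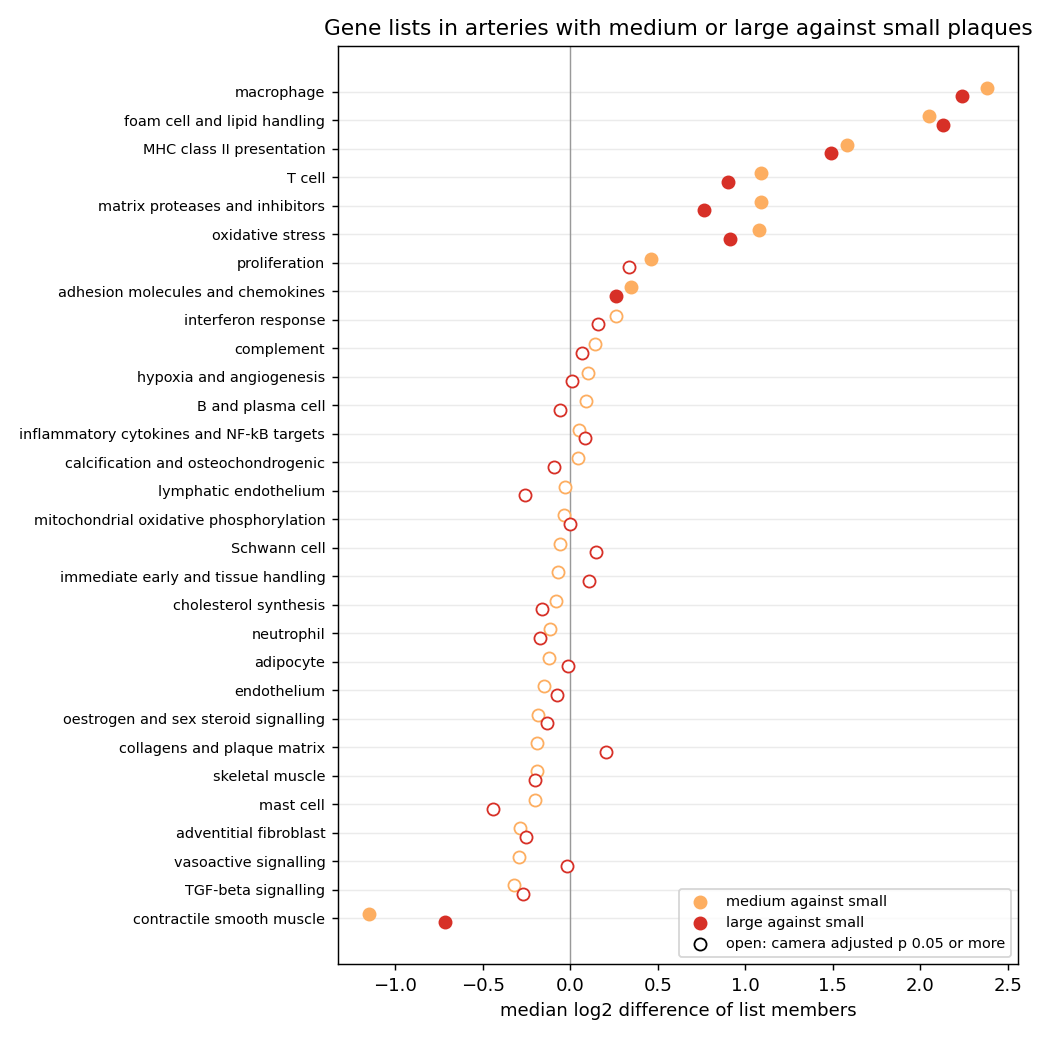
Median log2 difference of the members of each of 30 lists, in arteries with medium plaque (orange) or large plaque (red) against small plaque, filled where camera's adjusted p was under 0.05. Macrophage genes lie highest, at 2.38 and 2.24, and contractile smooth muscle genes lowest, at -1.15 and -0.714.

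**Figure D2:**
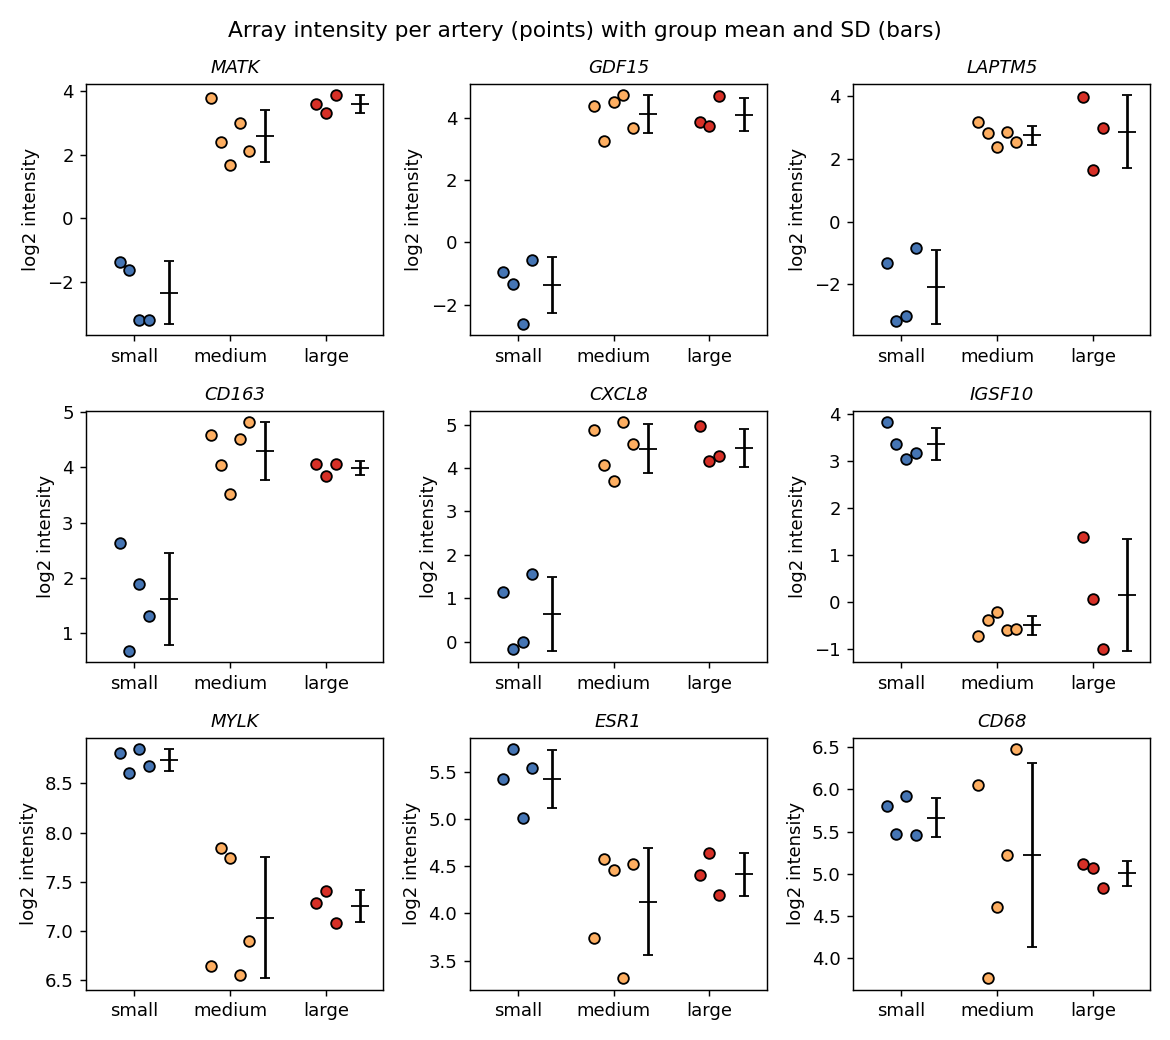
Log2 intensity of 9 genes in each artery, points by plaque group, with the group mean and SD beside them; the intensity axes differ between panels. For the first 5 genes every medium and large artery lies above every small one, for IGSF10, MYLK and ESR1 below, and for CD68 the groups overlap.

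Large and medium plaques were compared directly to ask whether further growth of the plaque came with further differences. No named gene passed. The genes of smallest p in each direction among brighter probes included CRIP2 at 2.12 ± 0.37 (SE, n = 3 and 5; adjusted p 0.448), TNFRSF12A at 1.73 ± 0.34, MTMR11 at -1.05 ± 0.22 and CDCA5 at -1.06 ± 0.26. KATNAL1, INPP5J, VSIR and ETV5 differed by 0.81, 0.88, -0.75 and -0.64. CD163 differed by -0.31 ± 0.40, MYH11 by 0.30 ± 0.19 and ESR1 by 0.29 ± 0.30.

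Camera called the immediate early and tissue handling list as higher in large plaques, with 14 of 15 members positive, a median of 0.311 and an adjusted p of 0.00287. DUSP1 differed by 1.22 ± 0.40 and JUN by 1.23 ± 0.43, neither past the threshold. The list's adjusted p was 0.203 with an estimated correlation, and 0.0872 without large replicate 1. The proliferation list was called as lower, with 3 of 18 members positive and a median of -0.327, and UBE2C at -1.12 ± 0.30 and BIRC5 at -0.70 ± 0.22. Its adjusted p was 0.519 with an estimated correlation, and 0.135 without medium replicate 1. No member of either list passed adjusted over the list alone.

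No probe was called by limma in large against medium, with 2713 at an unadjusted p under 0.05 against 2694 expected by chance and a lowest adjusted p of 0.0628. The count was 3 without small replicate 1, and 1 without large replicate 2, medium replicate 1 or small replicate 3. Lists called were 1 without large replicate 1 or medium replicate 1 and 4 without large replicate 3. The 28 lists not called had adjusted p-values from 0.182 to 0.994.

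Plaque area itself was then used in place of the groups. The genes with the steepest positive slope were MATK at 7.18 ± 1.13 log2 units per mm2 (SE, n = 12), GDF15 at 6.75 ± 1.36, MLPH at 6.43 ± 1.11 and LAPTM5 at 6.38 ± 1.17. CRABP2, CTSS, LY86 and LYZ followed. A slope over 12 arteries does not separate a graded rise from a step between small and the others. Between large and medium MATK differed by 1.00, GDF15 by -0.009, MLPH by 0.05 and LAPTM5 by 0.11, none past the threshold. Lysosomal and lipid genes were among those that rose, CTSD at 4.17, CHIT1, chitotriosidase, at 4.12 and GPNMB at 2.73. CRYM fell by 3.53 ± 0.70, ECRG4 by 3.25 ± 0.58 and COL27A1 by 3.00 ± 0.57 per mm2. WFDC1 at -2.80 with 1 large array at the floor, TLN2 at -2.55, MPRIP at -2.13, TBC1D13 at -2.08 and PHYHIPL at -2.04 fell as well. The calls of GDF15, CRYM and TBC1D13 were lost under 13, 15 and 14 of 22 alternatives. Those of LYZ, COL27A1, MPRIP and LAPTM5 were lost under 12, 11, 11 and 10 of 22, and that of WFDC1 under 12 of 21. Every other gene named in this paragraph lost its call under at least 6.

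Of the macrophage markers 5 of 18 rose with area, and 13 rose and 1 fell adjusted over the list alone, with ITGAX at 3.59, TYROBP at 3.92, CD86 at 4.12, LYZ and LAPTM5 (adjusted p 0.261 with an estimated correlation). The calls of TYROBP and CD86 were lost under 12 and 11 of 22 alternatives. Foam cell genes rose in 6 of 22, and in 16 adjusted over the list alone, and oxidative stress genes in 4 of 16, namely GPX1 at 3.00, GPX3 at 2.42, CYBA at 3.83 and HMOX1 at 2.52, whose call was lost under 13 of 22 alternatives, and in 9 adjusted over the list alone. Both lists had an adjusted p of 0.261 with an estimated correlation. Matrix proteases rose in 4 of 20, CTSS, MMP19 at 3.10, CTSK at 2.08 and PLAUR at 2.45, and 10 rose and 2 fell adjusted over the list alone (adjusted p 0.317 with an estimated correlation). MHC class II genes had no call over all probes and 6 rises and 1 fall adjusted over the list alone, CIITA, named after its values were seen (adjusted p 0.317 with an estimated correlation). T cell markers had 0 and 7 rises (adjusted p 0.346 with an estimated correlation), and adhesion molecules and chemokines 1, CXCL8 at 4.90, and 5 (adjusted p 0.439 with an estimated correlation). That last call ended without small replicate 1, at an adjusted p of 0.0628, and without small replicate 2, at 0.0512. It also ended with fry, at an adjusted p of 0.0751, and with the mean of all probes of a gene, at 0.102. Contractile smooth muscle, called as lower, had 0 falls over all probes and 3 adjusted over the list alone (adjusted p 0.346 with an estimated correlation), with MYLK at -2.00 ± 0.48 not passing.

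The slope was called for 314 probes, 260 higher and 54 lower, and 8 lists were called, 7 higher and 1 lower. With an estimated correlation none of these 8 lists was called. The probe count was 0 without large replicate 3, 1 without small replicate 2, 1 without small replicate 4, 21 without small replicate 3, 92 without large replicate 2, 102 without small replicate 1, 134 without medium replicate 5, 182 without medium replicate 3, 746 without medium replicate 1 and 0 without both animals whose identity numbers lie apart, small replicate 4 and medium replicate 5. The other 22 lists had adjusted p-values from 0.138 to 0.97.

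Scores of 4 lists were set against plaque area, and adjustment was over these 4 relations. The macrophage score was -1.37 ± 0.39 in small (SD, n = 4), 0.665 ± 0.366 in medium (n = 5) and 0.711 ± 0.347 in large (n = 3), and the foam cell score -1.44 ± 0.106, 0.713 ± 0.435 and 0.73 ± 0.423. The contractile smooth muscle score was 0.61 ± 0.167, -0.416 ± 0.491 and -0.12 ± 0.396. In these 3 scores the small arteries lay apart from all others, so no correlation over all 12 is given for them. Within the 8 arteries with medium or large plaque the macrophage r with area was 0.376 (exact permutation p 0.357) with rho 0.405 (exact permutation p 0.327). The foam cell r there was 0.312 (exact permutation p 0.443) with rho 0.167 (exact permutation p 0.703). The contractile smooth muscle r was -0.128 (exact permutation p 0.757) with rho -0.0952 (exact permutation p 0.84). The 4 small arteries alone were too few for a correlation.

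The T cell scores of the groups overlapped. Over the 12 animals r was 0.728 (permutation p 0.00792, adjusted 0.0106) and rho 0.578 (permutation p 0.0525, adjusted 0.0525), so the rank relation did not pass. Without the 2 animals farthest from the median area r was 0.762 (permutation p 0.0143). Within the 8 arteries with medium or large plaque it was 0.0667 (exact permutation p 0.881; rho -0.286, exact permutation p 0.501).

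**Figure D3:**
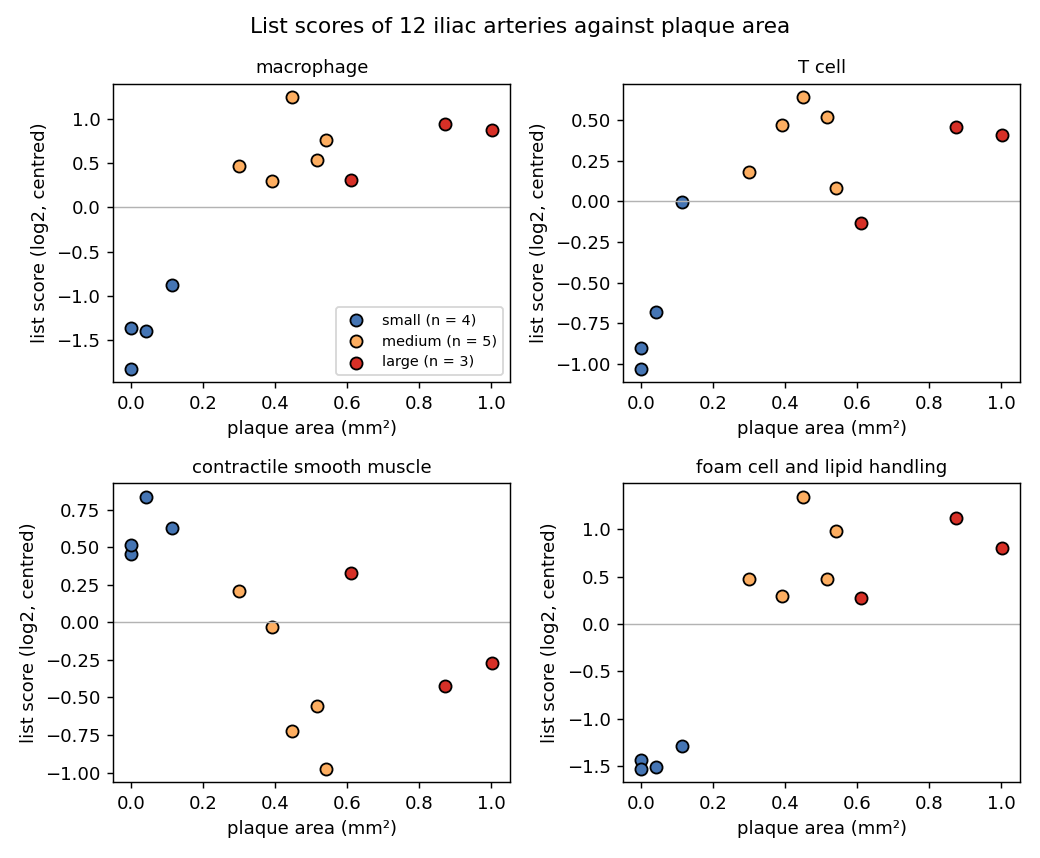
Score of 4 gene lists (mean log2 intensity of members, each centred over the 12 arteries) against plaque area in mm2, with 1 point per artery coloured by plaque group. The macrophage and foam cell scores of the 4 small arteries lie below all others, and among the other 8 the points show no slope that passed its test.

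Any difference among the 3 groups was called for 1062 probes, 1047 of them also called in a comparison against small. The count was 365 without small replicate 2, 609 without large replicate 1, 673 without medium replicate 5 and 382 without both animals whose identity numbers lie apart.

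The comparisons of large and of medium against small called 482 probes in common in the same direction, 424 higher and 58 lower, with none in opposite directions. Independent lists of these sizes would share 10.1 higher and 1.24 lower. Both comparisons use the same 4 small arrays. Unchanged groups simulated 100 times against shared arrays had no shared calls, which cannot show what shared arrays add among probes that differ. In these simulated groups the correlation of log2 differences across probes ran from -0.624 to 0.956 with a mean of 0.455. That range holds the observed 0.78, so the correlation was not beyond what unchanged groups gave. Their covariance had a mean of 0.0546 and reached 0.225, against an observed 0.239, a difference of 0.184 from the mean. With the small arrays split so that each comparison used 2 of its own, 85 to 203 probes were shared in the same direction and at most 2 in opposite directions, the correlation was 0.356 to 0.487 and the covariance 0.143 to 0.178.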

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

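Of 302 sets of small or medium arteries examined, covering list scores, array summaries and named genes, 13 had an artery far from the rest of its group, against 15.1 expected by chance. In each case the gap to the nearest artery is given as a share of the group's range. No explanation was tested for these values.

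In small replicate 1, CD3D, a T cell receptor subunit, stood at 3.94 against 1.98 to 2.08 in the other small arteries (share 0.946), and CYP27A1 at 2.84 against 1.93 to 1.98 (0.942). In small replicate 4, ADAMDEC1 was higher at 0.90 (0.888), and COL1A1 at 2.32 (0.906), TNNT3 at -0.22 (0.865) and TIMP3 at 2.59 (0.833) were lower than in the others. In small replicate 3, CRIP2 was higher at 1.59 (0.871) and CHIT1 at 2.41 (0.841). In small replicate 2, CRYM was higher at 5.27 (0.875). In medium replicate 1, LYZ was higher at 7.96 (0.765) and CYBA at 1.86 (0.743). MLPH was lower in medium replicate 2 at 4.69 (0.735), and the score of collagens and plaque matrix was lower in medium replicate 4 at -0.53 (0.735).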

How the results depend on the processing

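All alternatives were planned, and no named call changed sign under any of them. Of the called genes named, 890 of 1057 values kept the call in large against small, 1460 of 1675 in medium against small and 386 of 703 in the trend. Of the list calls, those of foam cell, MHC class II and adhesion genes in medium against small held in all 20 alternatives. Quantile normalization gave 605, 1594, 1 and 330 probes for large against small, medium against small, large against medium and the trend. The cause of each change below was not tested, except that some alternatives use fewer arrays or probes.

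Large against small (617) gave 1397 with probes above the median mean signal only (950 higher, 447 lower), 1161 with a variance trend and robust fit, 1254 with array weights, 316 without the 2 animals whose identity numbers lie apart (small replicate 4 and medium replicate 5), 379 with only the 2 groups compared, 605 higher and 281 lower with a pseudocount against 511 and 106, 1747 at an adjusted p under 0.10 and 6975 at an unadjusted p under 0.05 with a 1.5-fold difference, of which 3432 were higher and 3543 lower, so that the excess of rises was absent there. Medium against small (1693) gave 773 without those 2 animals, 3200 and 7230 (3344 higher, 3886 lower) at the other thresholds. Large against medium (0) gave 1 with quantile normalization, 2 with 1 probe per gene, 3 with array weights, 4 with only the 2 groups compared, and 1 and 2256 at the other thresholds. Any difference (1062) gave 1776 with brighter probes, 1666 with the variance trend, 382 without those 2 animals, and 2284 and 7658 at the other thresholds. The trend (314) gave 607 with a pseudocount, 1121 with brighter probes, 656 with 1 probe per gene, 777 with the variance trend, 0 without those 2 animals, 70 with group codes, 1942 with log2 of area, and 1498 and 7917 (3658 higher, 4259 lower) at the other thresholds.

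With each animal left out in turn, counts ran from 112 to 1216 for large against small, 847 to 1567 for medium against small, 0 to 3 for large against medium, 365 to 1097 for any difference and 0 to 746 for the trend. Lists called ran from 8 to 9, 9 to 10, 1 to 4 and 7 to 9 for large against small, medium against small, large against medium and the trend. With an estimated correlation 0, 3, 0 and 0 lists were called, and with fry 8, 15, 0 and 7. Shared calls against small (482) were 1193 at an adjusted p under 0.10 and 1052 with brighter probes.

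The replicate numbers name separate animals. Of 10 same-numbered pairs of arrays in different groups, 4 had residuals correlated above 0.1, with a range from -0.159 to 0.216. Their median was 0.0824, against -0.0228 in the 37 other pairs, so an effect shared by replicate number was not excluded. A replicate block gave 448, 866, 0, 540 and 0 probes for large against small, medium against small, large against medium, any difference and the trend, and 9, 9, 2 and 8 lists. Values near the floor limit what dim probes can show.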

Other observations

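The tests of a lower smooth muscle share, of scaling between arrays, of proportion to plaque area and of single animals were chosen only after the results were seen, as was the subtraction of the differences that proportion needs.

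In several lists that camera did not call, a few members were called. In medium plaques 2 of 15 hypoxia and angiogenesis genes rose, LDHA at 1.39 and NDRG1 at 1.04, and 1 fell, ANGPT2 at -1.34. Of 17 TGF-beta signalling genes 3 fell, TGFB2 at -1.02, ID1 at -1.74 and SMAD4 at -0.89. In large plaques TGFB1 rose by 2.14 ± 0.45, a call lost under 12 of 23 alternatives. Of 14 complement genes 2 rose in medium plaques, CFB by 2.83 and CD55 by 1.42. On the brightest probe of each gene ESAM, at -1.41, was the only endothelial marker of 14 called there. Of 11 skeletal muscle markers 2 were lower, TNNC2 at -1.38 and TNNT3 at -0.68. Of 15 inflammatory cytokine genes 2 rose, among them TLR4 by 2.80, and of 16 interferon response genes 1 rose, IFI44L by 0.96. Camera called neither list. In medium plaques fry, which does not compare a list with other genes, called the lists of hypoxia (adjusted p 0.0294), complement (0.018), inflammatory cytokines (0.00918) and interferon response (0.00906) as higher, but not those of TGF-beta signalling (0.104), endothelium (0.0852) or skeletal muscle (0.0951). Of these calls in medium plaques, those of LDHA, TNNC2, ANGPT2 and IFI44L were lost under 13, 12, 10 and 10 of 23 alternatives and that of TNNT3 under 13 of 22. Those of CFB, SMAD4, TGFB2 and ESAM were lost under 8, 8, 6 and 4 of 23 and that of ID1 under 5 of 22, whereas NDRG1, CD55 and TLR4 kept theirs under all 23.

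Of 18 macrophage genes 14 were higher in medium and 14 in large than in small arteries, and so were all 22 foam cell genes. Over all probes 11 macrophage and 15 foam cell genes passed in medium, and 10 and 12 in large. With an estimated correlation, camera still called only the foam cell list in medium among these. A lower share of smooth muscle would raise the markers of every other cell type alike, if those cell types kept their proportions to each other. The macrophage score minus the endothelium score was 2.26 higher in the 8 arteries with more plaque (exact permutation p 0.00202, the smallest this split allows). The macrophage score alone already parted these arteries from the small ones, in a list picked because it had risen. That p therefore adds nothing on the smooth muscle share. The endothelium score, which a lower share would raise in that case, differed by -0.212 in the same 8 arteries against the small ones (exact permutation p 0.0182). The contractile smooth muscle score was itself lower, at -0.416 in medium and -0.12 in large against 0.61 in small. Only endothelium was set against the macrophage score, so a lower smooth muscle share was not excluded. Scaling between arrays was argued against by the macrophage median difference in medium, 2.47 with quantile normalization and 2.38 without. More macrophages or foam cells in the tissue and higher expression per cell both stay open as untested hypotheses, which bulk tissue may not separate.

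The macrophage score, a mean of log2 values, differed between large and medium arteries by 0.0461 (exact permutation p 0.839). If the log2 score itself were in proportion to area, large would lie 1.97 times as far from small as medium does, but the macrophage ratio was 0.519 of that, from 0.486 to 0.559 with each animal left out, and the contractile smooth muscle ratio 0.361, from 0.295 to 0.415. A relative transcript level, taken as 2 to the power of the macrophage score, was examined as well. In proportion to area it needs a smaller log2 difference of 0.79 between large and medium. Its ratio was 0.523 of the area ratio, from 0.48 to 0.613 with each animal left out. Each array was scaled to a median near 1, so this level is relative to the artery's other transcripts and is not an amount. Such a level need not follow area in proportion even where the amount does, so an amount in proportion was not excluded. Too few arrays is an unlikely reason only if both needed differences are taken as known. The measured scores less either difference gave an exact permutation p of 0.0179, the smallest that 3 against 5 allows. Both differences were estimated from these same arteries, and that error is not in the p, so a smaller needed difference is not excluded. The share of 1000 simulated sets that passed, 0.999, was for the larger difference and alone excludes nothing. A response reached early that then levels off is a candidate explanation, untested because no artery was sampled more than once.

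Camera called immediate early genes as higher and proliferation genes as lower in large than in medium arteries, but their adjusted p was 0.203 and 0.519 with an estimated correlation, fry called neither, and no member passed. The immediate early score differed by 0.467 (exact permutation p 0.0179, the smallest the 56 splits allow), in a list picked because it was called. Its adjusted p was 0.0872 without large replicate 1, so that animal may carry the call, although fewer arrays alone can also end one. The scores of large replicates 2 and 3, 0.114 and 0.275, also lay above every medium score, the highest being -0.0416. This argues against a score difference that rests on large replicate 1 alone. The proliferation score differed by -0.297 (exact permutation p 0.196), and its adjusted p was 0.135 without medium replicate 1, so chance or that animal could account for it. Handling of the tissue at biopsy and a biological difference between the groups stay open, untested.

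Regrouping the arrays tested whether chance could give as many calls. In medium against small 1 of 100 splits, the real one, gave 1693 probes, with 62 the highest of the others, and for any difference among the groups 1 of 100 gave 1062, with 4 the highest other, so chance was excluded for both. For the trend 2 of 100 reassignments of area, the real one included, gave as many as 314. The other called 827, for a reason that was not examined. The share was small, but a reassignment with that many calls means that chance was not firmly excluded. The trend count was also 0 without large replicate 3. In large against small 2 of 35 splits gave as many as 617. The other called 630 with small replicates 2, 3 and 4 set against small replicate 1 and the large arrays. That split keeps the real grouping except for small replicate 1, so it holds most of the real difference. The next highest split called 4 probes. The count of 2 of 35 therefore cannot decide whether chance gave the calls. In large against medium all 56 splits gave 0 or more, the highest other 5. List counts did not exclude chance: 2 of 35 splits for large against small (8, highest other 8), 9 of 100 for medium against small (9, highest other 11), 34 of 56 for large against medium (2, highest other 10) and 9 of 100 for the trend (8, highest other 10).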
